A study of Homo sapiens with 6 samples.

How the data were processed

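RNA-seq libraries of poly(A) RNA were made from U251 control cells (3 libraries) and U251 cells with short hairpin knockdown of HNRNPA2B1 (3 libraries), with dUTP marking of the second strand, per the labels' protocols. The sequence of the hairpin, how it was delivered, the control construct and whether the libraries came from separate cultures are not given in the sources used here, so p-values measure the spread between these libraries, which may be technical.

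The deposited table held, per library, a whole-number count and an FPKM for each of 36440 Ensembl genes, per the file headers. The counts are raw counts per gene as deposited, and whether they are reads or fragments, the aligner, the counter and the use of strand in counting are not given in the sources used here, so overlapping and antisense genes are uncertain. The FPKM values are used as deposited and are named FPKM in the file headers. The headers do not state which gene length or library total was used. Over 10189 genes with at least 500 counts in every library, the ratio of count to FPKM per total count varied between libraries with a median coefficient of variation of 0.47%, so both columns hold the same information. Per the submitters' processing notes the genome build was mm10, a mouse build, while the table lists human genes. Of the 36440 identifiers, 35247 are in GENCODE 29 (GRCh38), and 99.97% of these overlap the same gene there, 78.6% with the same start (tolerance 0 bp). Coordinates are those of the table, which fit GRCh38. The table held 12 other per-sample columns, named for another cell type, which match no sample here and were not used.

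Groups were taken from the labels, and columns were matched to samples by name. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries scaled by TMM and knockdown compared with control by the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. The design fixed before the data were examined assumed FPKM values and limma, with the edgeR count test in its place if the table held counts; as it did, the count test was used and the planned pseudocount, scaling and trend settings for FPKM became alternatives fitted with limma 3.58.1, while the filters on low FPKM were applied to the counts in edgeR. The total count per library ranged from 78066160 to 85104392, and the biological coefficient of variation was 0.188. Replicates were not duplicates of one library: their chi-square per degree of freedom lay between 15.8 and 23.3. For a gene with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group, with the count of the other group taken as observed.

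Before the data were examined, 48 gene lists were fixed for glioma, hnRNP function, signalling, metabolism and other cell types, with 1046 distinct members, 15 of them absent from the table. Lists with at least 5 tested members, HNRNPA2B1 left out, were tested with camera (limma) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, each adjusted over the lists. GO terms were those of the table's own annotation, not propagated to parent terms. Terms of 10 to 500 members among the 11796 tested genes with a term were tested for over-representation by a one-sided Fisher test per direction. That test treats genes as independent and makes no allowance for correlation between them. The genes named were HNRNPA2B1, HNRNPA1, HNRNPA3, EGFR, STAT3, CD44 and VIM, the 12 largest rises and 12 largest falls among changed protein-coding genes with non-overlapping groups, the 3 most abundant in each direction, and up to 4 members of each list and of the leading terms, of which a part is printed. Some results are not reported. As the largest changes were all at very low counts, the same rule was also applied to genes with an FPKM of at least 1 in at least 3 libraries, a choice made after seeing the data. In the largest changes, 477 changed genes with a placeholder name or of another type than protein coding were skipped. The blood genes, chosen after hemoglobin counts were seen, and the chromosome windows (10 Mb, at least 20 expressed genes, 2000 random draws per window size) are outside that rule.

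The tests were run on simulated counts with the real means and dispersions and 200 changed genes in each of 10 draws. The changed genes were picked among those not at low levels. For knockdown against control, over 18095 genes on average, edgeR recovered 31.8% of 1.25-fold, 64.8% of 1.5-fold, 82.2% of 2-fold and 97.4% of 4-fold changes, and 8.25% of its calls were unchanged genes, above the 5% aimed at. For DESeq2 that share was 19.4% and for limma 9.01%. The data called 6302 genes, far more than the 200 changed in a draw, so these shares may not carry over. Of simulated lists, 5 of 5 shifted and 0 of 15 unshifted ones were called, and of simulated terms 5 of 5 and 1 of 15. Each gene was drawn independently and members were picked at random. These results therefore do not test lists or terms whose genes move together.

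Alternatives were DESeq2 1.42.0, pseudocounts of 0.1 and 0.5, other filters on low values, rescaling to 1000000, median and quantile normalization, limma without trend or with a robust trend, a 2-fold minimum, the replicate number as a block and each library left out in turn. Added after seeing the data were limma on log2(FPKM + 1), scaling by library totals, an FPKM filter in edgeR, a correction for transcript length and GC content, and removal of the regional shift, in which the running median of log2 fold change over 101 neighbouring expressed genes was set as an offset of the knockdown libraries. That offset was treated as known, so tests in this setting leave out its own error. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Differential splicing and intron retention, known roles of hnRNP proteins, were not analysed here, since the values are per gene.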

Results

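Poly(A) RNA of U251, an established human glioma cell line, was sequenced in 6 libraries: 3 of control cells and 3 of cells in which HNRNPA2B1 was knocked down with a short hairpin RNA. HNRNPA2B1 encodes an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein (hnRNP) family. The libraries held 78066160, 80231642 and 80160343 counts in the control group and 85080111, 78869938 and 85104392 in the knockdown group. Of the 36440 genes listed, 4429 had 0 counts in these libraries and 18764 had enough counts to be tested. The comparison asked which transcripts differed between knockdown and control cells. Levels are TMM-scaled counts per 1000000 (CPM), given as mean ± SD (n = 3 libraries per group), and log2 fold changes of knockdown against control are given ± SE.

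HNRNPA2B1 itself (ENSG00000122566, chromosome 7, 26173057 to 26201529, minus strand, coordinates as listed with the counts) fell from 1729 ± 47 to 428 ± 7.49 CPM, which left 24.8% of the control level. The log2 fold change was -2.01 ± 0.025 (edgeR adjusted p = 5.73e-11), and the 3 knockdown libraries lay below the 3 control libraries. An exact two-sided permutation test of the group means gave p = 0.1, the smallest value that 3 against 3 allows. Both close paralogs rose. HNRNPA1 went from 970 ± 12 to 1617 ± 18.2 CPM (log2 0.74 ± 0.018, edgeR adjusted p = 5.76e-09) and HNRNPA3 from 498 ± 10.6 to 774 ± 13.8 CPM (log2 0.64 ± 0.025, edgeR adjusted p = 6.87e-08). Reads of these genes can be shared with near-identical pseudogenes, and how such reads were counted is not given in the sources used here, so their levels are uncertain to that extent. STAT3, a transcription factor activated by cytokine receptors, fell from 222 ± 4.99 to 130 ± 5.97 CPM (log2 -0.77 ± 0.039, edgeR adjusted p = 4.19e-07). CD44, a hyaluronan receptor, fell by less, from 1720 ± 14.6 to 1437 ± 31.6 CPM (log2 -0.26 ± 0.02), and so did the intermediate filament gene VIM, from 6028 ± 140 to 5308 ± 70.4 CPM (log2 -0.18 ± 0.018). The call of VIM ended under quantile normalization with limma (adjusted p = 0.233, log2 fold change -0.22 to -0.13 over 21 alternatives). The growth factor receptor gene EGFR stood at 311 ± 24.7 CPM in control and 338 ± 10.3 CPM in knockdown cells and did not pass the test (edgeR adjusted p = 0.0945). It passed without control 3 (edgeR adjusted p = 0.0018), with the replicate number as a block (0.0366) and with DESeq2 (0.0119), with log2 fold changes of 0.092 to 0.20 over 21 alternatives.

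**Figure D1:**
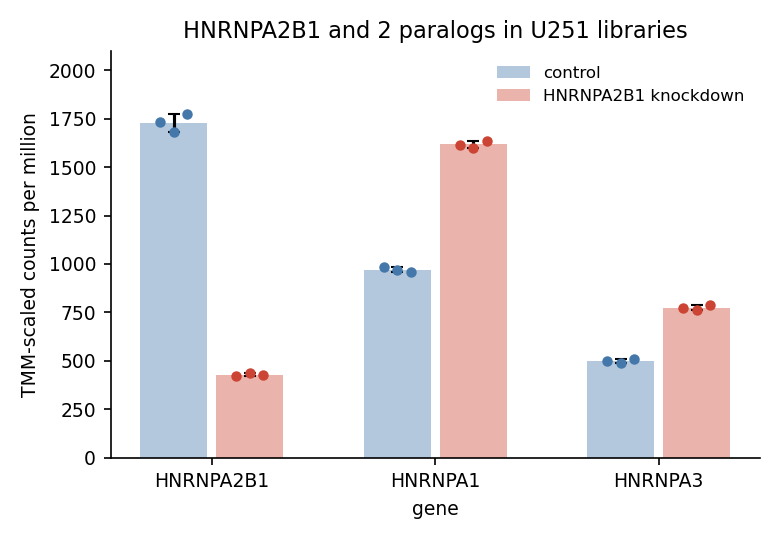
TMM-scaled counts per 1000000 of HNRNPA2B1, HNRNPA1 and HNRNPA3 in control (blue) and knockdown (red) libraries; bars show the mean, whiskers the SD and points the 3 libraries of a group. HNRNPA2B1 fell from 1729 ± 47 to 428 ± 7.49 CPM, while HNRNPA1 rose to 1617 ± 18.2 and HNRNPA3 to 774 ± 13.8 CPM.

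Knockdown cells differed from control cells at 6302 genes, 33.6% of those tested, of which 3149 were higher and 3153 lower. Most shifts were small: the median size was 1.24-fold among the higher and 1.32-fold among the lower genes, and 383 rose and 521 fell by at least 2-fold. The groups did not overlap at 46.8% of tested genes, against 10% by chance for 3 against 3. Among the 11599 tested genes with an FPKM of at least 1 in at least 3 libraries, 2794 rose and 2599 fell, 143 and 165 of them by at least 2-fold. Among these expressed genes the largest rises included the adhesion molecule gene ICAM1 (from 1.54 ± 0.209 to 22.1 ± 1.92 CPM, 14.3-fold, edgeR adjusted p = 3.08e-08), the stress-response gene IER3 (from 3.08 ± 0.564 to 40.9 ± 1.65 CPM, 13.2-fold) and the transcription factor gene EGR1 (from 11.7 ± 0.881 to 142 ± 1.82 CPM, 12.2-fold, edgeR adjusted p = 3.79e-10). CHST15, a chondroitin sulfate sulfotransferase gene, rose from 0.541 ± 0.151 to 8.99 ± 0.395 CPM and DHRS2, a dehydrogenase/reductase gene, from 2.93 ± 0.405 to 32.4 ± 0.587 CPM. The phosphatase gene PTPRE rose from 2.16 ± 0.41 to 15.6 ± 1.05 CPM and ZCCHC12 from 0.714 ± 0.137 to 6.2 ± 0.526 CPM. C5orf46 rose from 0.142 ± 0.0703 to 2.09 ± 0.203 CPM. Of these, ICAM1, CHST15, DHRS2, PTPRE, ZCCHC12 and C5orf46 had log2 fold changes of 3.84, 4.05, 3.47, 2.85, 3.12 and 3.86, and of 2.24, 0.98, 1.81, 0.85, 1.40 and 1.13 at their smallest in limma on log2 FPKM, where a pseudocount of 1 shrinks changes at low levels. Their direction and call held there.

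The embryonic globin gene HBE1 rose from 0.166 ± 0.0354 to 3.63 ± 0.274 CPM and the olfactory receptor gene OR51B4 from 0.0705 ± 0.0278 to 2.05 ± 0.404 CPM. The listed model of HBE1 (chromosome 11, 5268345 to 5505604, minus strand) spans that of OR51B4 (5301014 to 5301946, minus strand), so counts of one can belong to the other. STX16-NPEPL1, a readthrough of 2 neighbouring genes whose counts depend on how shared exons were assigned, rose from 0.265 ± 0.141 to 13.3 ± 11.8 CPM, with a spread between knockdown libraries close to its mean, and its log2 fold change went from 5.64 to 4.63 without knockdown 1. In this group, HBE1, OR51B4 and STX16-NPEPL1 had log2 fold changes of 4.43, 4.83 and 5.64, and of 1.85, 1.41 and 1.69 at their smallest in limma on log2 FPKM.

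The largest falls among expressed genes, apart from HNRNPA2B1, included the calcium-binding protein gene EFHD1 (from 4.49 ± 0.916 to 0.501 ± 0.328 CPM), the aldo-keto reductase gene AKR1B10 (from 10.9 ± 0.462 to 1.54 ± 0.104 CPM, 7.09-fold, edgeR adjusted p = 2.26e-07), SCUBE3 (from 21.2 ± 1.55 to 3.27 ± 0.648 CPM) and the growth hormone receptor gene GHR (from 8.36 ± 0.183 to 1.32 ± 0.123 CPM). LINGO2 fell from 11.2 ± 1.49 to 2.02 ± 0.148 CPM and the organic anion exporter gene ABCC2 from 33.3 ± 2.25 to 6.16 ± 1.57 CPM. HMGN5, which encodes a nucleosome-binding protein, fell from 12.1 ± 1.57 to 2.32 ± 0.527 CPM and the transcription factor gene DACH1 from 20.2 ± 1.64 to 4.52 ± 0.716 CPM. LSAMP, which encodes a limbic system cell adhesion protein, fell from 22.7 ± 1.25 to 5.35 ± 1.14 CPM and PCSK1N from 3.14 ± 1.07 to 0.698 ± 0.35 CPM. By the same measure, EFHD1, AKR1B10, SCUBE3, GHR, LINGO2, ABCC2, HMGN5, DACH1, LSAMP and PCSK1N had log2 fold changes of -3.15, -2.83, -2.70, -2.67, -2.48, -2.43, -2.39, -2.16, -2.09 and -2.17, and of -1.11, -1.89, -1.33, -0.84, -1.36, -1.51, -1.58, -1.32, -1.04 and -1.08 at their smallest in limma on log2 FPKM. Among the most abundant changed genes, the translation elongation factor gene EEF1A1 rose from 11760 ± 311 to 13970 ± 183 CPM and the actin gene ACTB from 4620 ± 72 to 5100 ± 133 CPM, and the annexin gene ANXA2 fell from 3493 ± 35.2 to 2941 ± 66.9 CPM. PKM, the pyruvate kinase gene of glycolysis on chromosome 15, rose from 5193 ± 81.7 to 5513 ± 52.7 CPM (log2 0.086 ± 0.014), and it was called lower once the shift shared with neighbouring genes was removed (log2 fold change -0.063). That lower call treats the removed shift as known without error. The call of PKM ended in 3 limma settings (highest adjusted p = 0.369, log2 fold change -0.063 to 0.11 over 21 alternatives).

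**Figure D2:**
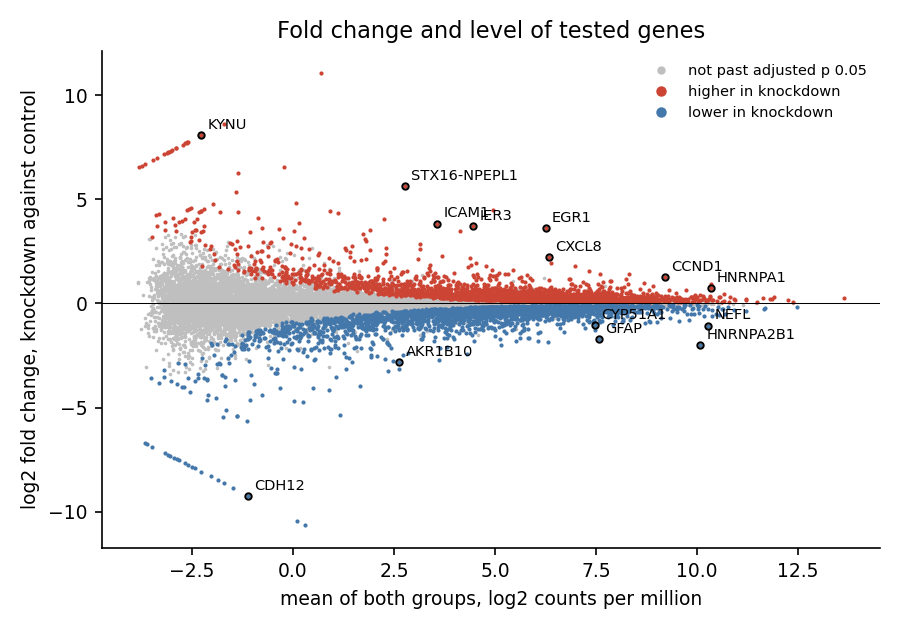
Log2 fold change of knockdown against control for each tested gene over its mean level in log2 counts per 1000000; red and blue points are the 3149 higher and 3153 lower genes and grey points did not pass the test. EGR1 (12.2-fold higher) and HNRNPA2B1 (24.8% of control left) stand out at high levels, and the lines of points at the left are genes with 0 counts in one group.

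Genes with 0 counts in one whole group included the largest fitted changes, 22 of them higher and 21 lower, and their folds are lower bounds computed against a floor of 3 counts over the group, which covers counting error of the group with 0 counts only. The count of the other group was taken as observed, so its error and spread are not covered. KYNU, an enzyme gene of tryptophan breakdown, was at least 32.9-fold higher (0.415 ± 0.124 CPM in knockdown cells) and the potassium channel gene KCNJ3 at least 26.2-fold. DCDC2C, BIN2, MEOX1, C16orf54, LPAR3, CD8A, SLC5A4, DES, SERPING1 and SIGLEC15 were at least 25.5, 24.6, 23.9, 19.8, 18.8, 18.5, 18.2, 17.2, 15.3 and 14.4-fold higher. CD8A is also one of 8 lymphocyte genes whose summed counts were 3, 10 and 13 in the control and 35, 86 and 76 in the knockdown libraries. Other genes of this higher set, such as BIN2 and C16orf54, stood at levels like that of CD8A. Whether RNA from blood cells raised them was not tested. In the other direction the cadherin gene CDH12 was at least 77.3-fold lower (0.925 ± 0.278 CPM in control cells), PAGE5 at least 59.5-fold, FSTL4 at least 46.3-fold, NOL4 at least 40.7-fold and DOK7 at least 21.9-fold. SLC1A2, which encodes an astrocytic glutamate transporter, fell from 0.896 ± 0.0436 to 0.0169 ± 0.0293 CPM, with all its knockdown counts in knockdown 2 (log2 fold change -5.65, and -9.19 without that library).

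Growth-factor and inflammatory response genes rose together. Of the ERK feedback targets, 14 of 18 members rose and 0 fell (14 and 0 adjusted over the list alone), with a camera adjusted p of 5.5e-26. Examples were the transcription factor gene ETV4 (from 3.64 ± 0.0999 to 10.6 ± 0.479 CPM) and the cyclin gene CCND1 (from 348 ± 13.9 to 842 ± 14.4 CPM, 2.42-fold). Of the immediate early genes, 15 of 20 members rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 3.34e-24). FOS went from 1.58 ± 0.488 to 8.29 ± 0.193 CPM and EGR2 from 0.166 ± 0.0915 to 1.86 ± 0.854 CPM. BTG2, the member that fell, went from 6.83 ± 0.453 to 2.23 ± 0.475 CPM. In limma on log2 FPKM the log2 fold changes of ETV4, FOS and BTG2 went down in size from 1.54, 2.39 and -1.62 to 0.94, 1.21 and -0.90. The ERK and immediate early lists share 3 tested members. Of the NF-kB targets and inflammatory cytokines, 17 of 24 members rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 1.21e-18), with ICAM1 among them. These 3 calls held with an estimated correlation between genes (adjusted p = 0.0452 with an estimated correlation for each). Of the senescence-associated genes, 10 of 15 members rose and 2 fell (10 and 2 adjusted over the list alone). Camera gave this list adjusted p = 2.01e-05, and adjusted p = 0.154 with an estimated correlation. The senescence list shares 2 tested members, CXCL8 and IL6, with the NF-kB list. The chemokine gene CXCL8 rose from 28.5 ± 3.97 to 133 ± 7.14 CPM (4.69-fold), the cytokine gene IL6 from 3.22 ± 0.684 to 13.9 ± 0.495 CPM (4.32-fold) and the collagenase gene MMP1 from 1.1 ± 0.962 to 4.58 ± 0.269 CPM (log2 fold change 2.06, 3.08 without control 3 and 1.01 at its smallest in limma on log2 FPKM).

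**Figure D3:**
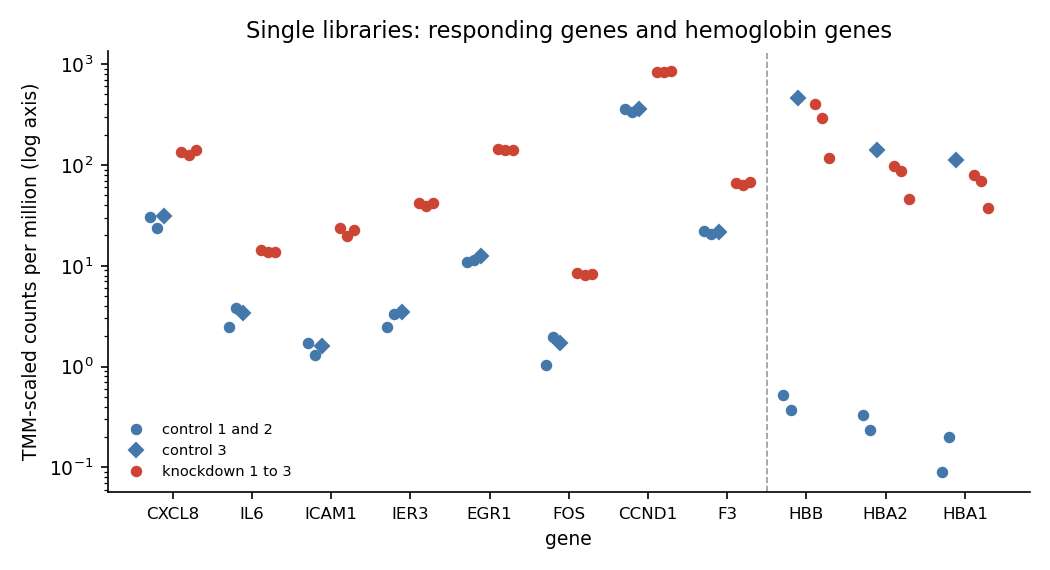
TMM-scaled counts per 1000000 (log axis) in each library of 8 genes that rose and of 3 hemoglobin genes; blue circles are control 1 and 2, blue diamonds control 3 and red circles the knockdown libraries. CXCL8, IL6, ICAM1, IER3, EGR1, FOS, CCND1 and F3 separate the groups, while HBB stands at 460 CPM in control 3 and at 0.524 and 0.371 CPM in control 1 and 2.

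Hemoglobin transcripts set some libraries apart from others and crossed the groups. The hemoglobin gene HBB stood at 0.524 and 0.371 CPM in control 1 and 2, at 460 CPM in control 3 and at 400, 294 and 117 CPM in the knockdown libraries. HBA1 and HBA2, which can share reads, were also highest in control 3 (111 and 141 CPM). The genes HBB, HBA1, HBA2, HBD, ALAS2 and SLC4A1 together held 78 and 65 counts in control 1 and 2, 57884 in control 3 and 48827, 35533 and 16931 in the knockdown libraries. A set of 8 neutrophil genes (FCGR3B, CSF3R, S100A8, S100A9, CXCR1, CXCR2, MNDA and LYZ) held 3 and 6 counts in control 1 and 2, 356 in control 3 and 984, 566 and 235 in the knockdown libraries. A set of 8 lymphocyte genes (CD3D, CD3E, CD2, CD8A, GNLY, NKG7, MS4A1 and CD79A) held 3 and 10 counts in control 1 and 2, 13 in control 3 and 35, 86 and 76 in the knockdown libraries. HBB did not pass the test between groups (edgeR adjusted p = 0.739). Of the microglia and leukocyte markers, 2 of 7 members rose and 0 fell (1 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.395, 0.0458 without knockdown 3 and 0.0204 with no filter on low levels). LAPTM5, a lysosomal protein gene of leukocytes, rose from 0.269 ± 0.188 to 1.83 ± 0.0935 CPM. Without control 3, 3156 genes were higher and 2757 lower, and 25 lists passed.

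Genes induced by hypoxia and those of glycolysis rose: 21 of 30 members rose and 0 fell (23 and 0 adjusted over the list alone), with a camera adjusted p of 6.11e-18 (adjusted p = 0.065 with an estimated correlation). NDRG1 rose from 55.7 ± 3.22 to 196 ± 7.93 CPM (3.52-fold), the glucose transporter gene SLC2A3 from 50.8 ± 0.817 to 109.6 ± 5.74 CPM and the carbonic anhydrase gene CA9 from 34.7 ± 2.26 to 72 ± 1.94 CPM. EGLN3, a prolyl hydroxylase gene of the oxygen-sensing pathway, rose from 15 ± 0.641 to 28.8 ± 1.91 CPM. Of the YAP targets, 15 of 20 members rose and 1 fell (16 and 2 adjusted over the list alone). By camera the adjusted p was 7.19e-11, and adjusted p = 0.1 with an estimated correlation. The largest rises were in the tissue factor gene F3 (from 21.4 ± 0.672 to 65.8 ± 2.1 CPM), ANKRD1 (from 18 ± 1 to 44.2 ± 2.71 CPM), DLC1 (from 19.9 ± 1.68 to 45.1 ± 4.3 CPM) and CCN1 (from 279.9 ± 8.59 to 551 ± 16.1 CPM). Of the ATF4 targets, 14 of 22 members rose and 2 fell (14 and 2 adjusted over the list alone). The camera adjusted p was 1.68e-10, and adjusted p = 0.0452 with an estimated correlation. The amino acid transporter gene SLC7A5 went from 81.1 ± 1.38 to 239 ± 3.34 CPM (2.95-fold), STC2 from 12.8 ± 0.431 to 34.4 ± 0.533 CPM and CHAC1, which encodes a glutathione-degrading enzyme, from 7.24 ± 1.41 to 15.1 ± 1.12 CPM.

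Genes of ribosomes and translation rose by small amounts. Among MYC targets and ribosome biogenesis genes, 19 of 26 members rose and 1 fell (20 and 1 adjusted over the list alone). Camera gave this list adjusted p = 4.68e-08, and adjusted p = 0.161 with an estimated correlation. MYC rose from 22.8 ± 2.07 to 45.6 ± 3.61 CPM (2-fold), the nucleolar gene NOLC1 from 176 ± 4.58 to 279 ± 6.52 CPM and DKC1 from 163 ± 1.83 to 244 ± 2.52 CPM. WDR43 rose from 58.6 ± 1.85 to 86.7 ± 1.79 CPM. Of the ribosomal proteins, 38 of 55 members rose and 0 fell (40 and 0 adjusted over the list alone), with a median log2 fold change of 0.15. By camera the adjusted p was 1.71e-06, and adjusted p = 0.41 with an estimated correlation. Examples were RPL22 (log2 0.48 ± 0.028), RPL4 (log2 0.37 ± 0.019), RPS24 (log2 0.35 ± 0.031) and RPS3 (log2 0.34 ± 0.033), which were 0.30, 0.24, 0.19 and 0.15 with the regional shift removed. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain in the same way as those of HNRNPA1. Over-represented Gene Ontology (GO) terms among higher genes were headed by viral transcription (59 of 95 members, 19.4 expected, adjusted one-sided Fisher p = 3.02e-15), a term made up largely of ribosomal proteins and nucleoporins such as NUP210 (from 122 ± 3.14 to 183 ± 6.57 CPM), NUP58 and NUP160. Translational initiation (72 of 130, 26.6 expected), nonsense-mediated decay (57 of 104, 21.3 expected), membrane targeting by the signal recognition particle (51 of 83, 17 expected) and translation (113 of 286, 58.5 expected) followed. Members past the test included the initiation factor genes EIF5B (from 119 ± 5.43 to 159.7 ± 9.38 CPM) and EIF5A2 (from 60.1 ± 1.83 to 85.3 ± 3.46 CPM), the decay factor gene UPF3B (from 40.7 ± 2.35 to 57.1 ± 2.13 CPM) and SRPRA, the signal recognition particle receptor gene (from 248 ± 5.11 to 357 ± 11.9 CPM). With the regional shift removed, the log2 fold change of EIF5B went from 0.43 to 0.16, that of SRPRA from 0.52 to 0.35 and that of NUP160 from 0.38 to 0.25. The Fisher test of GO terms, here and below, treats genes as independent. Its p-values can be too small where members of a term move together.

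**Figure D4:**
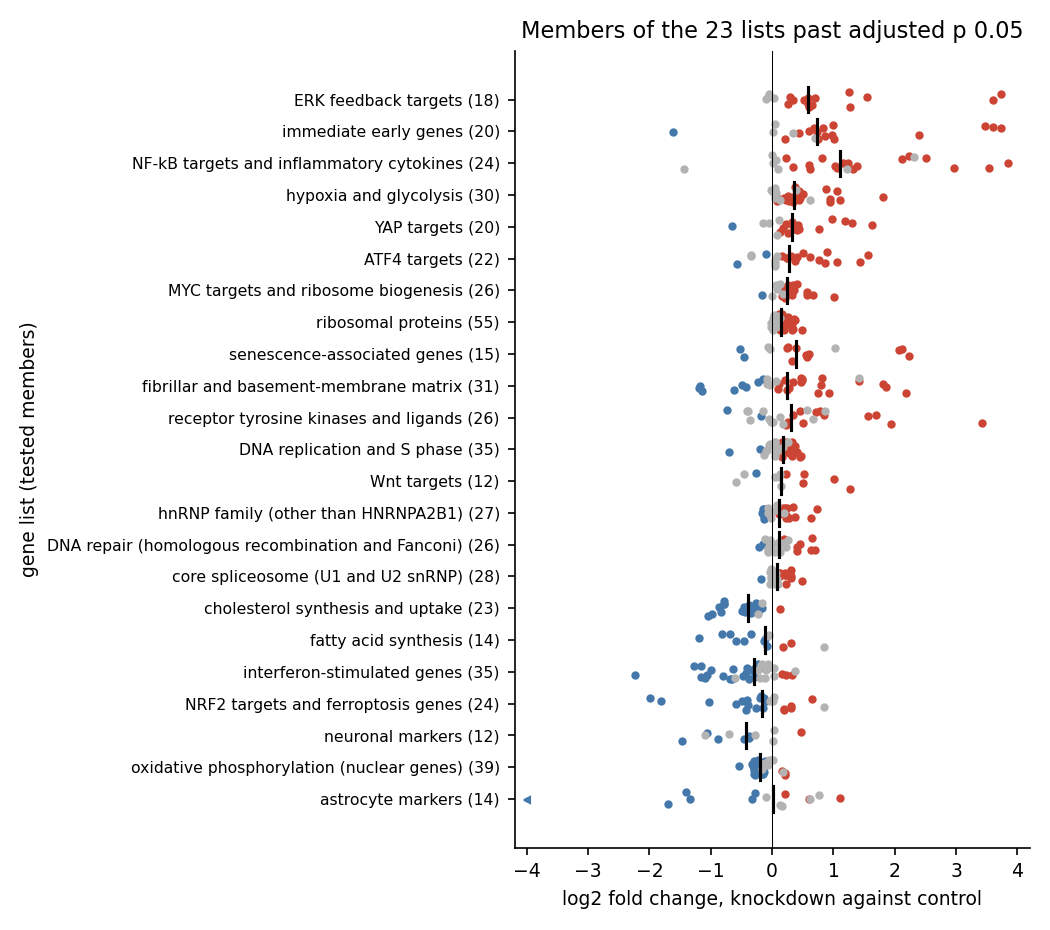
Log2 fold change of knockdown against control for the tested members of the 23 gene lists that passed camera; red and blue points are members that rose and fell, grey points did not pass, black bars are list medians and the arrowhead at the left edge is a member beyond the axis (SLC1A2). ERK feedback targets (median 0.59), immediate early genes (0.74) and NF-kB targets (1.11) lie furthest to the right and neuronal markers (-0.42) furthest to the left.

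Lipid synthesis genes fell. Of the genes of cholesterol synthesis and uptake, 1 of 23 members rose and 20 fell (1 and 22 adjusted over the list alone). The camera adjusted p was 1.37e-18, and adjusted p = 0.0477 with an estimated correlation. CYP51A1, the lanosterol demethylase gene, fell from 239.6 ± 6.11 to 116 ± 2.08 CPM (log2 -1.05 ± 0.033) and SREBF2, which encodes the transcription factor of the sterol pathway, from 192 ± 3.83 to 97.5 ± 5.63 CPM. HSD17B7 fell from 20.7 ± 0.936 to 11.3 ± 0.388 CPM. Of the fatty acid synthesis genes, 2 of 14 members rose and 9 fell (2 and 9 adjusted over the list alone). Camera gave this list adjusted p = 3.01e-06, and adjusted p = 0.101 with an estimated correlation. SREBF1 fell from 44.1 ± 0.844 to 19.4 ± 0.557 CPM and the acetyl-CoA carboxylase gene ACACA from 221 ± 9.16 to 125 ± 2.85 CPM. The stearoyl-CoA desaturase gene SCD fell from 790.4 ± 17.8 to 493 ± 4.68 CPM and the fatty acid synthase gene FASN from 283 ± 7.72 to 187 ± 6.18 CPM. The GO term cholesterol biosynthetic process was over-represented among lower genes (15 of 24, 5.01 expected, adjusted one-sided Fisher p = 0.00231).

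Nuclear genes of oxidative phosphorylation also fell, by small amounts: 3 of 39 members rose and 27 fell (4 and 28 adjusted over the list alone), with a median log2 fold change of -0.19. By camera the adjusted p was 0.000241, and adjusted p = 0.196 with an estimated correlation. The ATP synthase gene ATP5PO went from 84.8 ± 1.25 to 58.3 ± 1.91 CPM and the complex I gene NDUFB10 from 39.2 ± 1.74 to 31.2 ± 1.77 CPM. NDUFA2, also of complex I, went from 32.7 ± 0.872 to 26.6 ± 0.979 CPM. The GO terms respirasome (33 of 64, 13.3 expected, adjusted one-sided Fisher p = 2.03e-05), electron transport from NADH to ubiquinone (25 of 49), mitochondrial inner membrane (119 of 394) and oxidoreductase activity (126 of 408) were over-represented among lower genes, with NDUFB1 (from 15.6 ± 1.89 to 10.2 ± 0.718 CPM) and NDUFB2 (from 84.5 ± 3.23 to 58.2 ± 1.36 CPM) among their members. Of the 13 mitochondrially encoded genes, 3 rose and 1 fell (3 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.226, 0.028 without control 2 and 0.0484 without control 3). MT-ND3 went from 144 ± 19.2 to 235 ± 9.56 CPM and MT-ND2 from 655 ± 93.8 to 1038 ± 78.2 CPM. Among NRF2 targets and ferroptosis genes, 5 of 24 members rose and 15 fell (5 and 15 adjusted over the list alone). The camera adjusted p was 3.18e-05, and adjusted p = 0.196 with an estimated correlation. The aldo-keto reductase genes AKR1C1 and AKR1C3 fell from 56.3 ± 3.55 to 14.2 ± 0.396 CPM and from 70.8 ± 5.34 to 20.3 ± 0.911 CPM, and these closely related genes can share reads. HMOX1, which encodes the heme-degrading enzyme, rose from 28 ± 2.21 to 44.2 ± 2.32 CPM.

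Interferon-stimulated genes fell: 3 of 35 members rose and 20 fell (3 and 21 adjusted over the list alone). Camera gave this list adjusted p = 4.92e-06, and adjusted p = 0.0477 with an estimated correlation. IFI27 went from 60.5 ± 1.94 to 25.1 ± 2.04 CPM and the antiviral gene RSAD2 from 1.54 ± 0.133 to 0.324 ± 0.127 CPM. The antiviral gene OAS1 went from 5.08 ± 0.82 to 2.28 ± 0.129 CPM. Of the neuronal markers, 1 of 12 members rose and 6 fell (1 and 7 adjusted over the list alone). By camera the adjusted p was 5.37e-05, and adjusted p = 0.065 with an estimated correlation. The neurofilament gene NEFL fell from 1678 ± 39.4 to 803 ± 18.6 CPM (log2 -1.06 ± 0.024), the tubulin gene TUBB3 from 227 ± 8.38 to 123 ± 7.76 CPM and the growth cone gene GAP43 from 6.07 ± 1.55 to 2.2 ± 0.176 CPM, while the enolase gene ENO2 rose from 119 ± 3.7 to 164 ± 3.88 CPM. Of the astrocyte markers, 3 of 14 members rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.0131, downwards, and adjusted p = 0.196 with an estimated correlation). Their median log2 fold change was 0.018 against a mean of -0.52. Among members that passed the gene test, SLC1A2 fell most (log2 fold change -5.65). It is near the floor, with 215 counts in the control and 4 in the knockdown libraries, and it pulls the mean down. The next largest falls were in the intermediate filament gene GFAP (from 289 ± 20.3 to 89.1 ± 12.2 CPM, 3.25-fold lower, edgeR adjusted p = 5.49e-07), the clusterin gene CLU (from 96.5 ± 4.87 to 36.6 ± 3 CPM) and NDRG2 (from 3.5 ± 0.255 to 1.39 ± 0.126 CPM). The astrocyte call held in 9 of 21 alternative settings (highest adjusted p = 0.311). The GO term nervous system development was over-represented among lower genes (89 of 262, 54.6 expected, adjusted one-sided Fisher p = 0.000144).

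Matrix genes moved both ways, with more rises than falls: 18 of 31 members rose and 8 fell (19 and 8 adjusted over the list alone). The camera adjusted p was 0.000141, and adjusted p = 0.065 with an estimated correlation. COL18A1 rose from 7.53 ± 0.642 to 34.2 ± 1.4 CPM (4.54-fold), COL1A1 from 12.3 ± 2.11 to 42.7 ± 1.83 CPM and the basement-membrane collagen gene COL4A1 from 106 ± 0.978 to 283 ± 8.54 CPM. In limma on log2 FPKM the log2 fold change of COL18A1 went from 2.18 to 1.37. Among receptor tyrosine kinases and ligands, 12 of 26 members rose and 2 fell (15 and 5 adjusted over the list alone). Camera gave this list adjusted p = 0.000233, and adjusted p = 0.065 with an estimated correlation. The EGFR ligand gene TGFA rose from 34.6 ± 3.68 to 133 ± 1.69 CPM (3.83-fold) and PDGFB from 4.88 ± 0.391 to 15.8 ± 0.781 CPM. Of the Wnt targets, 5 of 12 members rose and 1 fell (6 and 1 adjusted over the list alone). By camera the adjusted p was 0.00554, and adjusted p = 0.196 with an estimated correlation. CCND1 and MYC were among the members that rose, and both are also in lists described above. These 3 calls held in 12 of 21, 20 of 21 and 14 of 20 alternative settings, with highest adjusted p of 0.127, 0.0751 and 0.088. The GO term focal adhesion was over-represented among higher genes (96 of 247, 50.5 expected), with the peptidase gene MME (from 18.6 ± 2.37 to 48.1 ± 4.54 CPM), the actin-bundling gene LCP1 (from 12.9 ± 0.495 to 31.4 ± 1.68 CPM) and EHD3 (from 3.55 ± 0.418 to 8.46 ± 0.445 CPM; log2 fold change 1.25, and 0.63 in limma on log2 FPKM) among its members. Of the integrins and focal adhesion list, 13 of 25 members rose and 5 fell (13 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.207, 0.0296 with no filter on low levels). ITGB3 rose from 21.6 ± 0.833 to 58 ± 1.85 CPM, whereas ITGB4 fell from 369 ± 12.7 to 196 ± 4.64 CPM and ITGA7 from 61.5 ± 1.92 to 26.7 ± 2.94 CPM.

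Genes of DNA replication and S phase rose by small amounts: 19 of 35 members rose and 2 fell (19 and 3 adjusted over the list alone). The camera adjusted p was 0.00234, and adjusted p = 0.299 with an estimated correlation. The ribonucleotide reductase gene RRM2 rose from 401 ± 10.2 to 554 ± 16.3 CPM and ORC1 from 31.8 ± 1.64 to 43.6 ± 3.17 CPM, while the chromatin assembly gene CHAF1B fell from 25.6 ± 0.519 to 15.7 ± 0.585 CPM. Of the list DNA repair (homologous recombination and Fanconi), 8 of 26 members rose and 2 fell (12 and 2 adjusted over the list alone). Camera gave this list adjusted p = 0.0204, and adjusted p = 0.465 with an estimated correlation. RAD54L rose from 28.6 ± 1.99 to 46.3 ± 1.56 CPM and the helicase gene BLM from 23.4 ± 1.65 to 36.1 ± 0.842 CPM. The DNA repair call ended without control 2 (camera adjusted p = 0.0571). Of the 35 mitosis genes, 7 rose and 6 fell (7 and 7 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.977). NDC80 went from 96.9 ± 4.21 to 80.8 ± 3.43 CPM. Among the hnRNP family other than HNRNPA2B1, 13 of 27 members rose and 5 fell (13 and 6 adjusted over the list alone). By camera the adjusted p was 0.00829, and adjusted p = 0.32 with an estimated correlation. After HNRNPA1 and HNRNPA3, HNRNPUL2 rose from 336 ± 7.75 to 433 ± 10.6 CPM and HNRNPDL from 159.8 ± 2.91 to 203 ± 2.01 CPM. Of the core spliceosome (U1 and U2 snRNP) genes, 12 of 28 members rose and 1 fell (12 and 1 adjusted over the list alone). The camera adjusted p was 0.0311, and adjusted p = 0.166 with an estimated correlation, and 0.0587 with the regional shift removed. SF3B6 rose (log2 0.31 ± 0.04, 0.12 with the regional shift removed). The DNA repair, hnRNP and spliceosome calls held in 9, 12 and 16 of 21 alternative settings (highest adjusted p of 0.261, 0.142 and 0.127).

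Other lists fixed for glioma and RNA processing did not pass camera in the reported setting, though members moved in either direction. Of the TGF-beta and BMP targets, 10 of 21 members rose and 7 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.0588), with PMEPA1 going from 174 ± 8.1 to 461 ± 13.5 CPM. The TGF-beta and BMP targets passed without control 1 (camera adjusted p = 0.0281), control 3 (0.0387) or knockdown 2 (0.0402), with DESeq2 (0.00619) and after correction for length and GC content (0.0343). Of the STAT3 targets, 6 of 16 members rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.117), with SOCS3 falling from 21 ± 0.388 to 13.3 ± 1.3 CPM. Of the epithelial-mesenchymal transition and mesenchymal glioma genes, 8 of 27 members rose and 10 fell (9 and 11 adjusted over the list alone; camera adjusted p = 0.869). RELB went from 8.49 ± 0.306 to 14.9 ± 0.87 CPM and LGALS3 from 44.4 ± 1.3 to 29.7 ± 2.93 CPM. Of the neural progenitor and glioma stem markers, 2 of 14 members rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.12). The neural progenitor and glioma stem markers passed downwards with DESeq2 (0.0425), with an FPKM of at least 1 (0.0332) or 5 (0.0195) in at least 3 libraries and after correction for length and GC content (0.0458). SOX2 fell from 172 ± 6.15 to 113 ± 1.46 CPM and POU3F2 from 73.8 ± 3.16 to 54.4 ± 2.11 CPM. Of the p53 targets, 3 of 24 members rose and 5 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.148), with RRM2B falling from 79 ± 0.41 to 51.2 ± 0.472 CPM. The p53 targets passed downwards with no filter on low levels (0.0479). Of the m6A writers, erasers and readers, 4 of 18 members rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.242). The reader gene IGF2BP2 rose from 122 ± 4.56 to 201 ± 3.46 CPM, and the eraser gene FTO fell from 87.6 ± 3.54 to 71.6 ± 1.99 CPM. Of the extracellular vesicle and endosomal sorting genes, 3 of 19 members rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.245). PDCD6IP fell from 238 ± 2.44 to 183 ± 1.39 CPM and CD63 from 678 ± 11.8 to 555 ± 7.88 CPM. For microRNA processing, 7 of 16 members rose and 2 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.564). DGCR8 rose from 35.7 ± 1.5 to 47.6 ± 0.234 CPM, and AGO4 fell from 29.9 ± 0.842 to 22.4 ± 0.75 CPM. For SR splicing factors, 3 of 14 members rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.667). SRSF2 rose from 147 ± 4.61 to 180.2 ± 6.84 CPM, and SRSF1 fell from 416 ± 13.7 to 346 ± 2.61 CPM.

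Lists of cell state and of other cell types were mixed as well, and none of the following passed camera. For Notch targets, 3 of 12 members rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.31), NOTCH2 going from 354 ± 10.9 to 415 ± 5.89 CPM. For ER chaperones of the unfolded protein response, 8 of 19 members rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.416). PDIA6 rose from 427 ± 7.66 to 596 ± 20.5 CPM, and CRELD2 fell from 18.4 ± 0.963 to 12.2 ± 0.905 CPM. For heat shock proteins, 6 of 15 members rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.627), with HSPB1 falling from 269 ± 1.85 to 198 ± 13.2 CPM. For matrix proteases and inhibitors, 10 of 29 members rose and 10 fell (10 and 10 adjusted over the list alone; camera adjusted p = 0.564), with TIMP3 rising from 1.26 ± 0.287 to 3.22 ± 0.538 CPM. For apoptosis effectors, 5 of 21 members rose and 4 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.564). BNIP3 rose from 214 ± 10.7 to 409.6 ± 10.1 CPM, and TNFRSF10B fell from 193 ± 1.51 to 139 ± 4.22 CPM. For apoptosis inhibitors, 3 of 10 members rose and 5 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.896). BIRC3 rose from 15.6 ± 2.64 to 34.8 ± 0.697 CPM, and BCL2 fell from 8.56 ± 0.373 to 6.38 ± 0.355 CPM. For lysosome and autophagy genes, 8 of 26 members rose and 7 fell (10 and 9 adjusted over the list alone; camera adjusted p = 0.872). The autophagy receptor gene SQSTM1 fell from 1662 ± 46.5 to 1169 ± 24.6 CPM, and the cathepsin gene CTSB rose from 843 ± 29.3 to 1135 ± 29 CPM. For antigen presentation by MHC class I, 4 of 15 members rose and 5 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.914), with TAP2 rising from 61.5 ± 0.138 to 85.5 ± 4.26 CPM. For replication-dependent histones, 0 of 22 members rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.564), and most of these transcripts lack a poly(A) tail. For endothelial markers, 1 of 7 members rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.834), with CDH5 falling from 2.71 ± 0.134 to 1.18 ± 0.0473 CPM. For oligodendrocyte markers, 1 of 5 members rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.977), with MYRF rising from 3.47 ± 0.15 to 6.6 ± 0.653 CPM. For epithelial markers, 2 of 5 members rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.416). In all, 23 of 48 lists passed, 16 upwards and 7 downwards, and 6 of them passed with an estimated correlation. For GO, 53 terms were over-represented among higher and 34 among lower genes, of 2177 tested.

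Fold changes were also shifted along whole stretches of some chromosomes. Expressed genes on chromosomes 10, 15, 11 and 2 had median log2 fold changes of 0.15, 0.13, 0.12 and 0.12, against -0.022 for the other chromosomes as a set. These 4 chromosomes held 900 higher and 290 lower expressed genes, against 1887 higher and 2304 lower on the others. In 10 Mb windows with at least 20 expressed genes, 44 of 227 medians differed from random draws of expressed genes (permutation test, Benjamini-Hochberg adjusted over windows, smallest p possible 5e-04). Of these 44 windows, 32 had medians above 0 and 12 below, and 29 lay on chromosomes 2, 10, 11 and 15. Lower windows included those from 110000001 (-0.26) and from 1 (-0.13) on chromosome 4 and from 120000001 (-0.14) on chromosome 7. On chromosome 1, the windows from 1 and from 10000001 had medians of 0.17 and 0.21 and that from 70000001 had -0.175. On chromosome 2, the 12 windows up to 140000000 had medians between 0.12 and 0.41 (439 genes, median 0.22), whereas the 9 windows beyond lay between -0.17 and 0.20 (321 genes, median -0.017), with 0.20 and 0.12 in the windows from 150000001 and from 160000001. On chromosome 10, the 8 windows from 40000001 onwards lay between 0.13 and 0.36. On chromosome 11, the 9 windows from 20000001 onwards lay between 0.061 and 0.28, and on chromosome 15 the 7 windows lay between 0.090 and 0.22. The medians of these chromosomes lay below the mean of the libraries in each control and above it in each knockdown library, such as -0.062, -0.083 and -0.061 against 0.077, 0.061 and 0.083 for chromosome 10. With the regional shift removed, 2866 genes were higher and 3089 lower, 83.5% of the calls were shared and 22 lists passed. Among genes named above, the log2 fold change then went from 0.57 to 0.37 for WDR43, from 0.47 to 0.28 for RRM2, from 0.37 to 0.24 for HNRNPUL2 and from 0.48 to 0.29 for PDIA6.

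**Figure D5:**
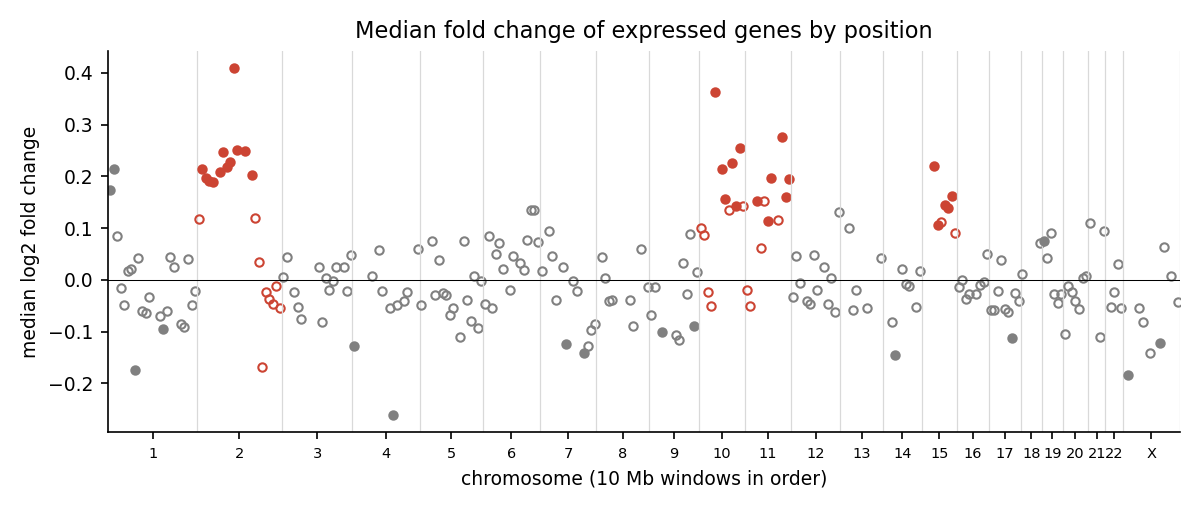
Median log2 fold change of knockdown against control over expressed genes in 10 Mb windows, ordered along the chromosomes; filled points passed the permutation test after adjustment and red points lie on chromosomes 2, 10, 11 and 15. On chromosome 2 the windows up to 140000000 have a median of 0.22 over their genes and those beyond of -0.017.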

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

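The added settings named in the methods were chosen only after the data were seen. HNRNPA2B1 kept its direction and its call in all 21 alternatives that refitted it (log2 fold change -2.03 to -1.99, highest adjusted p = 2.07e-06). With edgeR on genes with an FPKM of at least 5 in at least 3 libraries, 2074 genes were higher and 2006 lower, as fewer genes (7004) were tested, and 32 terms passed. With a minimum of 2-fold, 383 were higher, 521 lower and 46 terms passed. The number of terms was 87 as reported, 56 with a pseudocount of 0.1, 55 with 0.5, 55 with limma on log2(FPKM + 1), 45 after rescaling to 1000000, 51 with equal medians, 47 with quantile normalization, 25 for limma without trend and 134 with no filter. The filters change the number of genes tested, and the limma settings each tested 11615 genes, fewer than the reported fit. That number does not account for the spread among the limma settings, and the cause was not tested. With an estimated correlation 6 lists passed. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.016, -0.047 and -0.048. With a replicate block, 2882 genes were higher and 2862 lower, 22 lists and 89 terms passed. Leaving out each library in turn gave 2690 to 3156 higher and 2456 to 2757 lower genes, 23 to 25 lists and 67 to 106 terms. DESeq2 called 3481 higher and 3301 lower genes, 98.9% of the reported calls among them. Scaling by library totals gave 2874 higher and 3460 lower. Calls shared with the reported ones had the same sign in each setting, except for 5 genes with the regional shift removed. In that setting the log2 fold change of PKM was -0.063. At this depth, 31.8% of simulated 1.25-fold changes were recovered, so small changes are listed only in part.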

Other observations

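The tests of RNA from blood cells, of an interferon-type response and of length and GC content on the NF-kB, immediate early and ERK lists were chosen only after the results were seen. Genes of cilia were over-represented among lower genes, with 17 of 36 members of intraciliary transport and 18 of 35 of the ciliary tip (7.51 and 7.3 expected, adjusted one-sided Fisher p = 0.0261 and 0.007). Of the term ATP synthesis coupled proton transport, 13 of 20 members were lower (4.17 expected, adjusted p = 0.00373), and of the term nuclear pore, 28 of 63 members were higher (12.9 expected, adjusted p = 0.00272).

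The number of changed genes was 6302. With 3 libraries per group there are 10 splits of the 6 libraries, too few for a share under 0.05: 1 split, the real one, gave as many genes, and the highest of the others gave 2. A copy-number difference between the cell populations was tested as the cause of most calls. Windows with a median of at least 0.25 in size held 2.46% of the changed expressed genes. That bound takes in 6 windows and lies above most of the regional shifts, so this share does not decide. The 44 windows past the test held 25.1%, so most changed expressed genes lay outside them. Chromosomes 2, 10, 11 and 15 held 22.1%, with 2227 of the expressed genes there and 9332 on the others. With the regional shift removed, 5955 genes were called, 5261 of them shared with the reported ones. This argues against regional copy-number shifts as the cause of most calls. An effect of the knockdown and any other difference between the cultures of the groups stay open.

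Genes of the NF-kB, immediate early and ERK feedback lists rose together. RNA from red cells and neutrophils as the cause is argued against by knockdown 3, which had 0.238 times the neutrophil level of knockdown 1 but 0.976 times its median log2 shift over the 59 members (bootstrap 95% interval 0.861 to 1.39), and RNA from lymphocytes by knockdown 1, with 0.381 times the lymphocyte level of knockdown 2 and 0.976 times its shift (0.758 to 1.15). These shifts were taken against the mean of control 1 and 2. Against that mean, control 3, with 356 neutrophil gene counts against 235 in knockdown 3, shifted by 0.0391. The mean of the knockdown libraries shifted by 0.618. The bootstrap intervals resample the members within a single pair of libraries, so they do not cover the spread between libraries. An interferon-type response to the hairpin vector is argued against by the median log2 fold change of the interferon-stimulated list, -0.30, with its camera call downwards. A trend with transcript length or GC content is argued against by the list medians after its removal. These were 1.11 for the NF-kB, 0.719 for the immediate early and 0.589 for the ERK list, against 1.11, 0.736 and 0.59 before. There was little trend to remove over expressed genes (Spearman rho of log2 fold change 0.0382 with length and -0.00588 with GC content). A response to the loss of HNRNPA2B1 is a hypothesis that stays open, as do an effect of the hairpin on other transcripts and a difference in culture density or medium, neither of which was tested.

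Fold changes shifted along chromosomes 2, 10, 11 and 15. A candidate explanation is a copy-number difference between the control and knockdown cell populations, as subclones of a cell line may differ. The 25th percentile of log2 fold change lay above that of the other chromosomes on each of the 4, by 0.123 at the lowest, but these chromosomes were chosen for their high medians, so this value does not decide, and the explanation stays open. A trend with length or GC content is argued against by the corrected chromosome medians, the lowest of which was 0.124. DNA was not measured here, and a regional effect of the knockdown itself was not tested and stays open too.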
